A study of Homo sapiens with 6 samples.

How the data were processed

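RNA was sequenced from 6 libraries labelled Huh7, a line derived from a human hepatocellular carcinoma. Of these, 3 came from cells kept at 21% oxygen (normoxia) and 3 from cells kept at 1% oxygen (hypoxia), both for 24 h. Per the labels' protocols, total RNA was depleted of ribosomal RNA, and strand-specific libraries were read from both ends. Per the submitters' processing notes, cutadapt, HISAT2 and RSEM were used with the GRCh38 (hg38) genome. Their versions, the annotation release and whether counting used the strand are not given in the sources used here.

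The authors deposited a single table with 251062 transcript rows named by Ensembl transcript identifiers, each with a length, an expected count and an FPKM value per library. The deposited expected counts are read counts divided among transcripts by RSEM and need not be whole numbers. They were the values used here. The 6 FPKM columns of the table were not used. Where FPKM is mentioned, it was recomputed from the expected counts and the deposited transcript lengths, which are not effective lengths. The column names gave each library's condition, and the numbers in them (C1 to C6) matched no replicate number in the labels. Libraries were therefore assigned to groups without a replicate number and are named here by their column (normoxia C1 to C3, hypoxia C4 to C6).

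Transcripts were summed per gene with GENCODE release 29 on GRCh38, the genome build the submitters name. A gene was found for 202907 rows, which gave 58478 genes, among them 19867 protein-coding and 15976 long noncoding RNA (lncRNA) genes. The other 48155 rows had no gene in that release and held 6.12% to 6.39% of each library's expected counts. They stayed out of library sizes and gene tests, so the sum of a gene with newer transcripts may be incomplete. Current symbols were found for 58184 genes. Genes were called lncRNA when they belonged to the long noncoding RNA annotation of the same release, which includes antisense and intronic transcripts. Reads of overlapping or antisense genes, of near-identical copies and of processed pseudogenes may have been divided between them.

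Gene sums of expected counts were rounded to whole numbers. Genes were kept by the default filterByExpr rule, scaled by TMM factors, and tested with edgeR's two-sided quasi-likelihood test (edgeR 4.0.16, limma 3.58.1, R 4.3.3). Benjamini-Hochberg adjustment covered the 17396 genes tested, with a threshold of 0.05. The standard error (SE) of a log2 change was taken as its size divided by the square root of the quasi-likelihood F. Levels are CPM, counts scaled to the TMM-adjusted library size. Where a group had 0 counts in its 3 libraries, the fold is given as a lower bound against a floor of 3 counts per library, which was 0.0757 CPM in normoxia and 0.0868 CPM in hypoxia. Such floors cover counting error only.

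The plan, fixed before the data were examined, foresaw limma on FPKM as the main test and edgeR in its place if the table held counts, which it did. It also foresaw summing transcripts to genes. It fixed 26 gene lists and the rule for named genes. The rule took the 10 risen and 10 fallen protein-coding genes with the largest log2 changes among genes past the threshold whose groups did not overlap, with a mean FPKM of 1 or more in a group, leaving out symbols that are clone names. It took 6 risen and 6 fallen lncRNAs in the same way at an FPKM of 0.5, with clone names allowed, up to 4 members of each list among those past the threshold (the 2 most expressed where none passed), and 27 genes regardless of result. The text leaves out some of these. Other genes named, such as CPS1, C3, PFKM, GAPDH, LDHA, RN7SK, PMVK, H2BC5, ALPI, ALPP, CGA, GAS5, SNHG3 and SNHG16, were chosen after their values were seen. Lists with 5 or more tested members were compared with other genes by camera with a preset inter-gene correlation of 0.01, and again with an estimated correlation. The fry test was run beside it.

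On simulated data, drawn for the hypoxia and normoxia comparison from each gene's mean over all libraries, its dispersion and the library sizes, 17016 genes were tested. Changes were given to genes of moderate to high counts. The edgeR test recovered 74.6% of 67 genes changed 1.5-fold, 91% of 67 changed 2-fold and 100% of 66 changed 4-fold. It called 14 of 16816 unchanged genes. Few genes were changed here, about equally in both directions, whereas 72.8% of the genes tested in the data changed. These rates therefore need not hold for the data.

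Expected counts summed to between 37621426 and 40794783 per library. Pairs of libraries within a group differed by more than sampling noise, with a chi-square over its degrees of freedom of 4.63 to 11.2, so no library was treated as a duplicate. Alternatives were DESeq2 1.42.0, other filters, other scalings, limma on log2(FPKM + 0.5) with other pseudocounts and weights, a test per transcript, and leaving out each library in turn. Scaling by library totals was added after the data were seen. Overlaps with annotated genes, the neighbourhoods of lncRNAs and exact tests were computed in Python 3.11.15 with scipy 1.17.1.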

Results

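The data are 6 rRNA-depleted RNA-seq libraries labelled Huh7, 3 from normoxia (21% oxygen) and 3 from hypoxia (1% oxygen, 24 h). The series title names an lncRNA induced by low oxygen and its role in ferroptosis, a form of cell death driven by iron and lipid peroxidation. The design allows 1 comparison, hypoxia against normoxia. Normoxia libraries C1 to C3 held 40119055, 40794783 and 39658910 expected counts, and hypoxia libraries C4 to C6 held 39627686, 39516753 and 37621426. Across genes, log CPM correlated at r = 0.987 to 0.991 within groups and 0.914 to 0.919 between them, where genes are not independent replicates. The first principal component held 84.7% of the variance and separated the groups. The labels call the replicates biological without describing the cultures, so p-values measure the spread between these libraries.

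The libraries labelled Huh7 held almost no mRNA of most listed genes that mark hepatocytes, the main cell type of liver. Albumin (ALB) had 6 counts over the 6 libraries together, and alpha-fetoprotein (AFP), apolipoprotein APOA1, transthyretin (TTR) and glypican GPC3 had 0. A count of 0 allows up to 0.0757 CPM in normoxia and 0.0868 CPM in hypoxia. Of 60 hepatocyte genes fixed in advance, 43 were below the filter, 48 were under 1 CPM in both groups and 14 had 0 counts in all libraries. Other members of the list were abundant, such as the urea cycle enzyme CPS1 at 2138 CPM in normoxia and 1773 CPM in hypoxia, and complement C3 at 332.8 and 488.4 CPM. Of the 17 tested members, 6 rose, 7 fell and 4 did not pass the edgeR test. The transcription factor HNF4A rose from 1.30 ± 0.181 to 7.01 ± 0.702 CPM (SD, n = 3), SERPINA1 from 0.067 to 1.83 CPM and the bile salt pump ABCB11 from 1.07 to 4.94 CPM. The list median log2 change was 0.15, with -0.001 under library totals and -0.25 under a filter of FPKM 0.5. HNF4A lost the call when its most abundant transcript was tested alone (log2 change 4.50). Some mRNAs outside the list, chosen after their values were seen, were abundant too. The intestinal alkaline phosphatase ALPI stood at 1449 CPM in normoxia and 3020 CPM in hypoxia, its placental homolog ALPP, which may share reads with it, at 190.8 and 136.4 CPM, and CGA, the alpha subunit of glycoprotein hormones, at 1316 and 904.8 CPM.

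Genes known as targets of the hypoxia-inducible factors (HIF) were higher in hypoxia. NDRG1, a stress-response gene, rose from 378.9 ± 7.01 to 7640 ± 203 CPM (SD, n = 3), a log2 change of 4.33 ± 0.04 (SE) or 20.2-fold. The peptide hormone gene ADM rose 44.4-fold, the oxygen sensor EGLN3 20.5-fold, carbonic anhydrase CA9 8.08-fold and the growth factor VEGFA 7.68-fold. The 49 tested of 54 HIF targets all rose, with a median log2 change of 2.57 and a lowest of 0.72, and 49 passed when adjusted over the list alone. RORA, at 0 counts in normoxia, was at least 6.52-fold higher. HIF1A mRNA, which encodes the HIF-1 alpha subunit, rose by 1.14-fold (log2 change 0.19 ± 0.06 SE) in the edgeR test and lost the call with library totals (log2 change 0.04) and without normoxia C1 (log2 change 0.13). EPAS1, encoding HIF-2 alpha, rose 1.88-fold. Of 18 tested HIF pathway components, 14 rose, 3 fell and 1 did not pass, among them ARNT2 with a rise of 4.51-fold and EGLN1 with 3.66-fold. The fallen members were CUL2, a ubiquitin ligase scaffold (from 14.3 to 4.75 CPM), ELOB and ELOC, while VHL had a log2 change of -0.13 and did not pass. CUL2 lost the call when its most abundant transcript was tested alone (log2 change -0.78), and its gene sum may miss newer transcripts.

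Glycolysis genes rose with few exceptions. Of 26 tested genes of glycolysis and glucose uptake, 25 rose and 1 fell, with a median log2 change of 1.73. Enolase ENO2 rose 14.2-fold, PFKFB4, a regulator of glycolytic flux, 12.9-fold, hexokinase HK2 9.42-fold, aldolase ALDOC 8.51-fold and the glucose transporter SLC2A1 7.47-fold. The muscle-type phosphofructokinase PFKM fell, from 169.6 to 57.7 CPM. GAPDH and LDHA rose as well, but processed pseudogenes exist for both and could have taken part of their reads. PDK1, a kinase that restrains pyruvate oxidation in mitochondria, rose 3.58-fold.

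**Figure D1:**
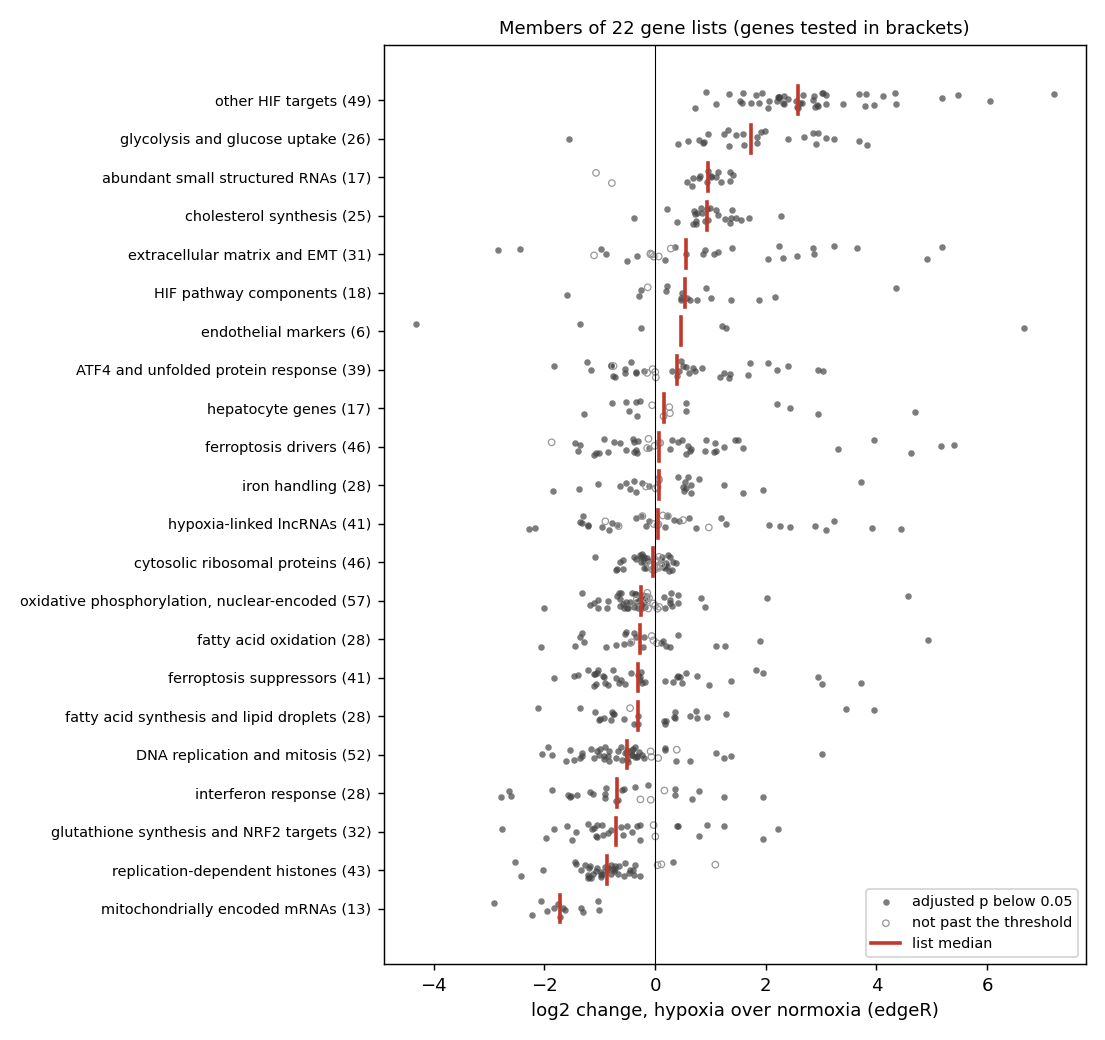
Log2 change (hypoxia over normoxia, edgeR; horizontal axis) of the tested members of 22 gene lists, with filled points past the adjusted threshold, open points not past it and red bars at list medians. HIF targets lie highest (median 2.57) and mitochondrially encoded mRNAs lowest (median -1.72), the medians of hypoxia-linked lncRNAs, ferroptosis drivers, iron handling and hepatocyte genes change sign under other scalings, and RORA and TEK, at 0 counts in normoxia, are drawn at fitted values.

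The mRNAs of the mitochondrial genome were lower in hypoxia. Of its 15 tested genes, 13 fell and 2, the rRNAs MT-RNR1 and MT-RNR2, did not pass. The median log2 change of these 2 rRNAs was -0.93, in libraries depleted of ribosomal RNA. Adjusted over the mitochondrial genome alone, 14 genes changed. All 13 mitochondrially encoded mRNAs fell, with a median log2 change of -1.72, and the mitochondrial genome's share of counts was 6.72% to 7.02% in normoxia and 2.37% to 2.48% in hypoxia. MT-ND6 fell by 2.92 on the log2 scale (SE 0.11) and MT-CYB by 1.96 (SE 0.05). Of 57 tested nuclear genes of oxidative phosphorylation, 35 fell, 12 rose and 10 did not pass, with a median of -0.25 and camera adjusted p = 0.0253, which became adjusted p = 0.444 with an estimated correlation. The ATP synthase gene ATP5MC1 fell 4.05-fold and ATP5PB 2.51-fold, whereas NDUFA4L2, a known HIF target, rose 23.9-fold.

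Over the whole transcriptome, 12669 of 17396 tested genes changed (72.8%), 6348 upward and 6321 downward, and 5018 changed at least 2-fold (3037 up, 1981 down). Under a filter of FPKM 0.5, which left 15436 genes, 4152 changed at least 2-fold in edgeR. With limma under that filter, the count was 4133 on log2(FPKM + 0.1), 3288 on log2(FPKM + 0.5) and 2609 on log2(FPKM + 1). A larger pseudocount shrinks the changes of low genes more. The groups did not overlap for 75.7% of genes, where chance gives 10%. Among protein-coding genes, 4560 rose and 5644 fell of 13140 tested. The split depended on the scaling. In edgeR with the same filter, the share of risen among changed genes was 50.1% with TMM, 41.2% with library totals and 40% with totals that left out mitochondrial and abundant small RNAs. In limma, which also used another unit and filter, it was 47.9% on FPKM scaled by median-of-ratios, 41.2% on FPKM, 35.7% on FPKM rescaled without those RNAs and 32.6% on TPM. The median log2 change of all genes was 0.025 with TMM and -0.13 with library totals in edgeR, and -0.12 on FPKM and -0.26 on TPM in limma, so small log2 changes hold relative to the scaling chosen. Without a low-count filter it was 0.13 in edgeR and 0.16 in DESeq2.

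By the fixed rule, the largest rises among protein-coding genes were of genes with no counts, or single counts, in normoxia. SLAMF9, a receptor of the immune SLAM family, reached 10.7 ± 0.571 CPM (SD, n = 3) in hypoxia and was at least 142-fold higher, and TREM1, a receptor of myeloid cells, was at least 42.3-fold higher. The calcium-binding S100A9 was at least 29.6-fold and S100A8 at least 8.56-fold higher, at 2.24 and 0.648 CPM in hypoxia. FAM153CP, TPSAB1 and FXYD2 were at least 161-fold, 16.6-fold and 16.4-fold higher, of which the first 2 belong to families of similar copies. PLA2G4D, a phospholipase A2, rose from 0.008 to 7.62 CPM, FAM177B to 3.61 CPM and WFDC5 to 3.03 CPM. The largest falls were of LGSN (35.9-fold), ANKRD2 (from 1.63 to 0.0593 CPM), the insulin-regulated glucose transporter SLC2A4 (25.2-fold) and the endothelial cadherin CDH5 (20-fold). ALPK2, RRS1, ANKRD1, KIAA0825 and MTARC1 fell 13.3-fold, 13.1-fold, 12.7-fold, 11.4-fold and 10.1-fold. The sizes for such low genes depend on the setting. The LGSN log2 change was -5.17 in edgeR, -5.81 without hypoxia C6, -1.79 with limma on log2(FPKM + 0.5) and -10.2 for its most abundant transcript. SLC2A4 and KIAA0825 overlap exons of a gene on the opposite strand.

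LncRNA genes, the subject of the series, changed mostly upward. Of 3032 tested, 1758 changed, 1290 upward and 468 downward, and 911 rose and 256 fell at least 2-fold. Adjusted over the lncRNAs alone, 1686 changed. Risen genes made up 73.4% of changed lncRNAs (exact 95% interval 71.2% to 75.4%) and 44.7% of changed protein-coding genes, an odds ratio of 3.41 (two-sided Fisher's exact test across genes, p = 1.41e-112, where genes are not independent). Genes of other biotypes, among them pseudogenes and small RNAs, had a similar share, with 498 risen and 209 fallen (70.4% risen). The lncRNA share was 66.8% with library totals in edgeR. In limma it was 66.9% on FPKM, 62.2% on FPKM rescaled without mitochondrial and small RNAs, 61.5% after quantile normalization and 58.5% on TPM. The median log2 change was 0.43 for lncRNAs, 0.43 for other biotypes and -0.08 for protein-coding genes. Under a filter of FPKM 1 or more, 1081 lncRNAs changed.

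**Figure D2:**
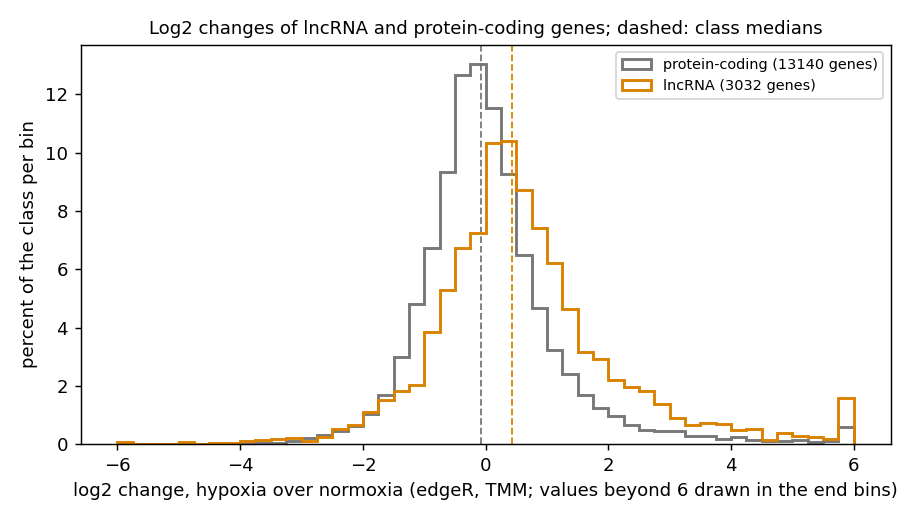
Distribution of log2 changes (hypoxia over normoxia, edgeR with TMM; horizontal axis) as the percent of each class per bin of 0.25 (vertical axis), for 13140 protein-coding and 3032 lncRNA genes. The dashed medians lie at -0.08 and 0.43.

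H19, an imprinted lncRNA gene (ENSG00000130600.18, chromosome 11, 1995176 to 2001470 on GRCh38), rose from 5122 ± 262 to 21310 ± 1314 CPM (SD, n = 3), a log2 change of 2.06 ± 0.05 (SE), and held 1.93% to 2.13% of counts in hypoxia. MIR210HG, the host of miR-210, rose 21.9-fold to 38.5 CPM, LINC01554 15.2-fold to 6.71 CPM and LUCAT1 (chromosome 5, 91054834 to 91314547) 9.36-fold to 538.4 CPM. The largest rises by the fixed rule were of ENSG00000266711 (at least 108-fold), ENSG00000285888 (at least 30.8-fold), LINC02178 (at least 16.3-fold), ENSG00000217825 (at least 12.3-fold), FLJ16779 (from 0.025 to 8.75 CPM) and ENSG00000279412 (chromosome 16, 70713987 to 70716890, from 0.134 to 45.5 CPM). The largest falls were of LINC00570 (at least 10.7-fold), TRG-AS1 (27.7-fold), ENSG00000272263 (from 0.613 to 0.029 CPM), ENSG00000278972 (17.2-fold), VPS9D1-AS1 (15.8-fold) and the snoRNA host SNHG4 (15.4-fold, from 78.1 to 5.07 CPM). The FLJ16779 level in normoxia and the ENSG00000272263 level in hypoxia lie under the floors for a count of 0. Over the alternatives, their log2 changes ran from 1.055 to 9.083 and from -5.11 to -1.1. VPS9D1-AS1 and SNHG4 overlap exons of protein-coding genes on the opposite strand, and SNHG4 also overlaps the tested protein-coding gene ENSG00000280987.4 on the same strand, so part of their reads may belong to those genes. MALAT1 (log2 change -0.16 ± 0.04 SE) fell in the edgeR test and was at 0.04 with quantile normalization. NEAT1 (log2 change -0.11 ± 0.03 SE) fell in the edgeR test and rose by 0.15 to 0.43 in limma on FPKM or TPM. Its mean CPM was 5250 in normoxia and 4853 in hypoxia, and its mean FPKM 758.8 and 946.1, so its direction depends on the unit. HULC, a lncRNA named for liver cancer, rose from 0.64 to 1.56 CPM, summed over 113 transcripts of a locus annotated from 8435568 to 9294133 on chromosome 6. That locus (ENSG00000285219.1) overlaps SLC35B3 on the opposite strand and lost the call with quantile normalization (log2 change 0.33).

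Of 62 lncRNAs linked to hypoxia or ferroptosis in advance, 57 were in the table and 41 were tested, of which 16 rose, 15 fell and 10 did not pass, 32 when adjusted over the list alone. The median was 0.06, with -0.09 under library totals, and camera gave adjusted p = 0.456. Several snoRNA host genes of the list fell, among them GAS5 from 42 to 8.59 CPM, SNHG3 from 231.1 to 90.5 CPM and SNHG16 from 34.5 to 13.9 CPM.

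**Figure D3:**
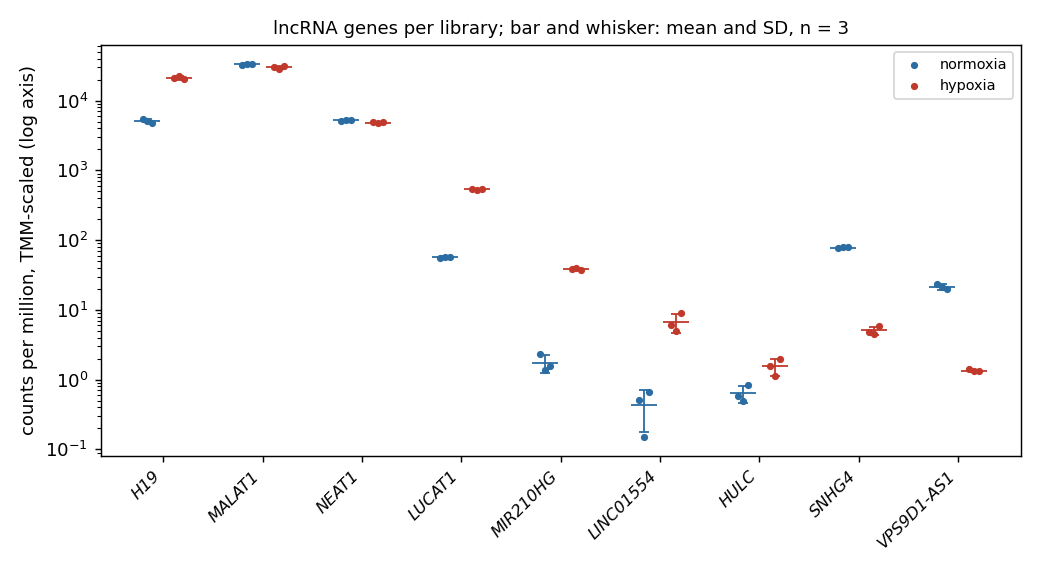
CPM (TMM-scaled, log axis) of 9 lncRNA genes in each library, with points for libraries and bars and whiskers for mean and SD (n = 3 per group). H19 lies near 5122 CPM in normoxia and 21310 CPM in hypoxia and SNHG4 near 78.1 and 5.07 CPM, while the direction of NEAT1 changes with limma on FPKM and that of MALAT1 with quantile normalization.

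Genes of ferroptosis and iron handling moved in both directions. The cystine importer gene SLC7A11 (ENSG00000151012.13, chromosome 4, 138164097 to 138242349 on GRCh38), which feeds glutathione synthesis, fell from 208.7 ± 13.9 to 59.1 ± 5.41 CPM (SD, n = 3), a log2 change of -1.82 ± 0.07 (SE). The ferritin heavy chain FTH1 rose from 2655 ± 36.8 to 10210 ± 516 CPM, although processed pseudogenes may share its reads, and FTL rose 1.33-fold, a call lost with limma on TPM (log2 change 0.09). GPX4, the glutathione peroxidase that reduces lipid peroxides, fell by 0.27 on the log2 scale (SE 0.05), and AIFM2, a quinone reductase that restrains ferroptosis, fell by 0.19 (SE 0.05) and lost the call with quantile normalization (log2 change -0.13). ACSL4, which activates polyunsaturated fatty acids, fell by 0.38 (SE 0.14) and lost the call without normoxia C1 (log2 change -0.28), hypoxia C4 (-0.26) or hypoxia C5 (-0.40) and for its most abundant transcript (-0.27). Heme oxygenase HMOX1 rose 2.36-fold and the transferrin receptor TFRC from 484.4 to 727.4 CPM. Transferrin (TF) rose 1.47-fold in the edgeR test, did not pass with limma on FPKM (log2 change 0.17) and had a log2 change of -0.03 with quantile normalization. TF overlaps exons of the tested gene SRPRB on the same strand, so part of its reads may belong to that gene. Of 101 tested genes in the ferroptosis and iron lists, 91 changed, 42 upward and 49 downward, as many as when adjusted over the list alone, and 18 rose and 18 fell at least 2-fold. Changed genes made up 90.1% of these lists, 77.7% of protein-coding genes and 72.8% of all genes. Levels were not matched in this comparison. Other lists had a higher share (all 25 cholesterol synthesis genes changed) or a lower one (14 of 46 ribosomal protein genes did not pass), so a high share is not particular to ferroptosis. The lists share members with others, such as CA9 and HILPDA with HIF targets and SLC7A11 and GPX4 with NRF2 targets.

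Among 41 tested ferroptosis suppressors, 15 rose and 26 fell, with a median of -0.31 and camera adjusted p = 0.109. The risen members included CP, encoding the ferroxidase ceruloplasmin (13.2-fold, from 0.438 CPM), the prominin PROM2 (7.73-fold) and CA9. Among 46 tested drivers, 22 rose, 18 fell and 6 did not pass, with a median of 0.08, or -0.07 under library totals, and camera adjusted p = 0.109. The lipoxygenase genes ALOXE3, ALOX15B and ALOX12B, which oxidize fatty acids, rose 42.3-fold, 35.9-fold and 24.7-fold to 20.4, 18 and 2.57 CPM, and HILPDA, a lipid droplet protein and HIF target, rose 15.5-fold. The 3 lipoxygenase genes lie on chromosome 17 (ALOX15B from 8039017, ALOX12B from 8072636 and ALOXE3 from 8095900). ALOX12B overlaps exons of a tested gene on the opposite strand. Among 28 tested iron-handling genes, 13 rose, 10 fell and 5 did not pass, with a median of 0.07, or -0.085 under library totals, and camera adjusted p = 0.216. The iron reductase STEAP3 rose 3-fold and the mitochondrial iron importer SLC25A28 fell 3.59-fold, although its most abundant transcript did not pass alone (log2 change -2.70). The liver iron hormone HAMP had almost no counts (0 CPM in normoxia and 0.01 in hypoxia). These genes were measured in libraries where 48 of 60 hepatocyte genes were under 1 CPM in both groups, while others, such as CPS1, were abundant.

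**Figure D4:**
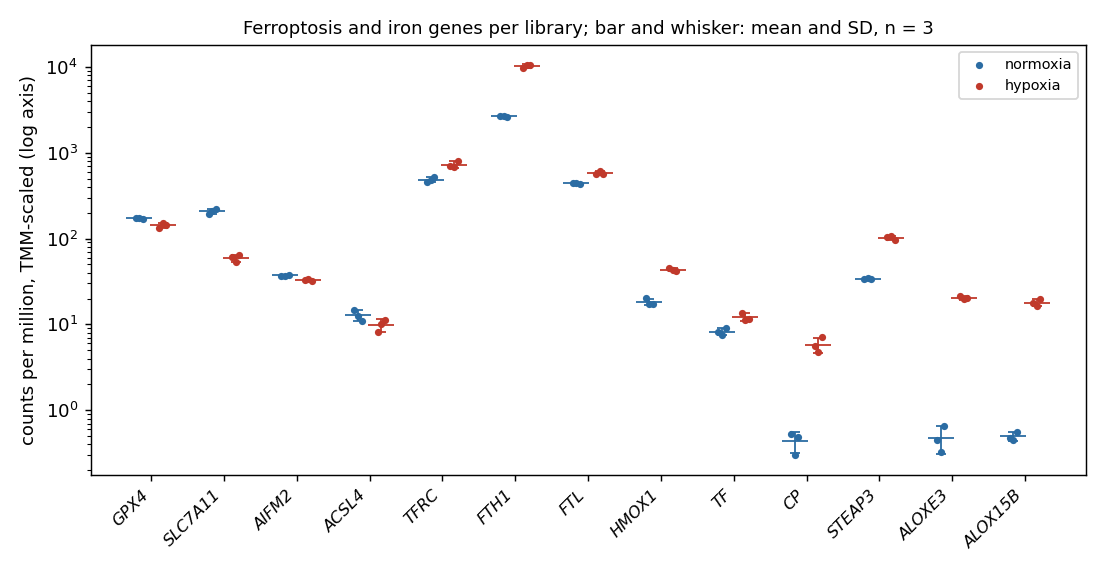
CPM (TMM-scaled, log axis) of 13 ferroptosis and iron genes in each library, with points for libraries and bars and whiskers for mean and SD (n = 3 per group). SLC7A11 lies lower in hypoxia (59.1 against 208.7 CPM) and FTH1 higher (10210 against 2655 CPM), while TF changes sign under quantile normalization.

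Genes of glutathione synthesis and the NRF2 response, which protect against oxidants, were mostly lower. Of 32 tested, 23 fell, 7 rose and 2 did not pass, with a median log2 change of -0.70 and camera adjusted p = 3.47e-05 (adjusted p = 0.0434 with an estimated correlation). The export pump ABCC2 fell 6.84-fold and SLC7A11 3.53-fold. OSGIN1 rose 4.64-fold. Cholesterol synthesis genes moved the other way, with 24 of 25 risen and 1 fallen (PMVK, log2 change -0.38), a median of 0.94 and camera adjusted p = 1.21e-10 (adjusted p = 0.0136 with an estimated correlation). INSIG1, a sterol sensor partner, rose 4.86-fold and the isomerase IDI1 2.95-fold, the latter without a call for its most abundant transcript (log2 change 0.45). The list of extracellular matrix and epithelial-mesenchymal transition genes holds epithelial members, such as CDH1 and EPCAM, beside mesenchymal ones. Of its 31 tested genes, 18 rose, 6 fell and 7 did not pass (median 0.55, camera adjusted p = 4.2e-10, adjusted p = 0.0434 with an estimated correlation). The collagenase MMP1 rose 30.3-fold, integrin ITGB4 12.6-fold and TGFBI 9.35-fold.

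Cell cycle genes were mostly lower. Of 52 tested genes of DNA replication and mitosis, 40 fell, 8 rose and 4 did not pass, with a median of -0.51. CDC20, an activator of anaphase, fell 4.14-fold, CDKN3 3.84-fold, POLE2 3.66-fold and the proliferation marker MKI67 1.25-fold. The risen members included CDKN1A (8.04-fold), CDKN1B and CDKN2D, which encode inhibitors of cyclin-dependent kinases. Of 43 tested replication-dependent histone genes, 39 fell, 1 rose (H2BC5, log2 change 0.32) and 3 did not pass (median -0.86), with H1-5 fallen 5.36-fold and H2AC16 5.81-fold. The camera call held with the preset correlation for both lists (adjusted p = 1.14e-05 and 1.08e-10) and was lost with the estimated one (adjusted p = 0.122 and 0.199). Of 28 interferon response genes, 19 fell, 6 rose and 3 did not pass (median -0.69, camera adjusted p = 8.47e-06, adjusted p = 0.0766 with an estimated correlation). HERC5 fell 6.90-fold, OASL 6.22-fold and IFIT2 6.09-fold, whereas IRF7 rose 3.87-fold. Of 39 genes of the ATF4 and unfolded protein responses, 21 rose, 13 fell and 5 did not pass (median 0.40, camera adjusted p = 0.00338, adjusted p = 0.11 with an estimated correlation), with STC2 risen 8.17-fold and GDF15 7.66-fold.

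Other lists did not pass camera. Of 28 tested fatty acid oxidation genes, 15 fell, 9 rose and 4 did not pass (median -0.28, adjusted p = 0.109), with the carnitine palmitoyltransferase CPT1A fallen 4.16-fold and BDH1 risen from 0.0845 to 2.67 CPM. Of 28 tested genes of fatty acid synthesis and lipid droplets, 14 fell, 13 rose and 1 did not pass (adjusted p = 0.684). Their median was -0.31 and their mean 0.03, and camera pointed up. The lipin LPIN2 rose 10.9-fold and the carboxylase ACACA fell 2.58-fold. Of 46 ribosomal protein genes, 19 fell, 13 rose and 14 did not pass (median -0.03, adjusted p = 0.284). Hepatocyte genes gave adjusted p = 0.684.

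Of 22 lists tested, 13 passed camera with the preset correlation and 7 with an estimated one, namely HIF targets, glycolysis, HIF pathway components, cholesterol synthesis, mitochondrially encoded mRNAs, NRF2 targets and extracellular matrix. For the first 3 the adjusted p with an estimated correlation was 0.000225, 0.0126 and 0.0209, and for mitochondrially encoded mRNAs it was 0.0329. The directional fry test, which does not compare a list with other genes, called 22 of 22. Adjusted over the list alone, the number of changed members was the same as over all genes for each list except 4, the hypoxia-linked lncRNAs (32), nuclear oxidative phosphorylation genes (49), small structured RNAs (16) and fibroblast markers (4). Some medians moved by more than 1.5 times with other tests and scalings. Settings that changed only the filter were left aside. DESeq2 and limma still came with their own filters, with 30375 genes tested in DESeq2 and 15436 in limma on log2(FPKM + 0.5). The lowest and highest medians were 0.26 and 0.56 for HIF pathway components, 0.57 and 0.94 for cholesterol synthesis, 0.10 and 0.40 for the ATF4 and unfolded protein responses, and 0.16 and 0.65 for extracellular matrix genes. They were -0.66 and -0.31 for ferroptosis suppressors, -0.54 and -0.25 for nuclear oxidative phosphorylation, -0.78 and -0.51 for replication and mitosis, and 0.60 and 0.96 for small structured RNAs. For lists that did not pass they were -0.59 and -0.26 (fatty acid synthesis), -0.53 and -0.23 (fatty acid oxidation) and -0.34 and -0.03 (ribosomal proteins). Under a filter of FPKM 1 in edgeR, the median was 0.93 for extracellular matrix genes, -0.03 for fatty acid synthesis and 0.009 for ribosomal proteins. Without a filter, the median for extracellular matrix genes was 0.63 in edgeR, near the 0.65 of DESeq2, and 0.067 in limma. For ribosomal proteins it was 0.005 without hypoxia C4.

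Most markers of other cell types were scarce, with exceptions such as COL1A1, CD68 and KRT7 (52.9 CPM in normoxia). None of 9 erythroid markers passed the filter. Of 14 immune markers, 4 were tested, of which CD68, a lysosomal protein also found outside macrophages, rose 7.49-fold to 46.4 CPM and CSF1R 12.7-fold to 4.85 CPM, while 10 lay below the filter and PTPRC had 0 counts. Of 6 tested endothelial markers, 3 rose and 3 fell (median 0.48, camera pointing down, adjusted p = 0.684), and the median was -2.25 under a filter of FPKM 1, with TEK at least 4.45-fold higher and VWF at 0.504 CPM in normoxia and 0.196 CPM in hypoxia, a call lost under 6 of 13 alternatives. Among these were the fits without normoxia C2 (log2 change -1.31), normoxia C3 (-1.33), hypoxia C4 (-1.09) or hypoxia C5 (-1.01). Of 4 tested fibroblast markers, 2 rose, 1 fell and 1 did not pass, and their median of 0.88 became -0.29 under a filter of FPKM 1. COL1A1 fell from 71.4 to 56.9 CPM and lost the call with limma on FPKM (log2 change -0.16), and COL1A2 had 0 counts. The 3 tested biliary and progenitor markers fell, KRT7 3.79-fold, CD24 3.25-fold and SOX4 1.73-fold.

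Small structured RNAs were more abundant in hypoxia. Of 17 tested, 15 rose and 2, the mitochondrial rRNAs MT-RNR1 and MT-RNR2, did not pass (median 0.96, camera adjusted p = 0.0253, adjusted p = 0.564 with an estimated correlation). The median log2 change of these 2 rRNAs was -0.93. RN7SK held 2.84% to 3.28% of counts in normoxia and 3.99% to 4.86% in hypoxia, and RNU1-1 rose 2.55-fold and RNU4-1 2.66-fold, both with near-identical copies.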

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

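Transcripts without a gene in the annotation used took no part in the gene comparisons, although some of them changed. When every transcript was tested with edgeR, 10997 such transcripts entered and 2567 of them changed (23.3%), 1437 upward and 1130 downward, 1944 by at least 2-fold. Over all transcripts, 21993 of 74527 changed. They were singled out because they lie outside the gene-level comparison, and whether they changed differently from transcripts with a gene was not tested. No explanation was tested for them.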

How the results depend on the processing

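The counts of changed genes, of ferroptosis and iron genes and of lists kept within 1.5 times the reported values in 95 of 101 recomputed counts. Leaving out each library in turn gave 11882 to 12439 changed genes, 1605 to 1732 lncRNAs, 86 to 91 ferroptosis and iron genes and 13 lists. The exceptions were lncRNAs and lists. For lncRNA genes changed, hypoxia against normoxia, there were 1758, and 1081 under an FPKM filter of 1 and 1036 with limma under that filter, where fewer genes were tested, 721 with lncRNAs defined by symbol and 1062 genes with a changed transcript in the test per transcript. Against 13 lists, 7 passed camera with an estimated correlation and 22 passed fry, which asks another question.

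For 123 of 142 named genes every alternative in which the gene was tested kept the direction and the side of the threshold. Low-level genes were tested in fewer alternatives, such as RORA and TEK in 12, against 25 for NDRG1. Of 3413 gene values, 59 lost the call and 13 reversed. NEAT1 reversed in 11 limma settings, with log2 changes of 0.32 on FPKM with pseudocounts of 0.5, 0.1 and 1, without filter, with a filter of FPKM 1 and without trend, 0.33 with array weights, 0.15 on TPM, 0.43 with median-of-ratios, 0.22 rescaled without mitochondrial and small RNAs and 0.26 after quantile normalization. After quantile normalization the TF log2 change was -0.032 and the MALAT1 log2 change 0.042. For NEAT1 the unit differed, as FPKM divides the counts of each transcript by its length and CPM does not. Shifts between NEAT1 transcripts were not examined, and no cause was tested for TF or MALAT1. HIF1A lost the call in 12 of 25 alternatives, TF in 9 of 23 besides its reversal, COL1A1 in 8, VWF in 6 of 13 and ACSL4 in 4. Scaling by library totals was chosen after seeing the data.

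No paired analysis was possible because the table's columns carry no replicate number of the labels, so the planned fit with a replicate block was not run. The planned settings on deposited FPKM used recomputed FPKM, and libraries were left out by column name. Depth limits statements on genes near 0: a count of 0 allows 0.0757 CPM in normoxia and 0.0868 CPM in hypoxia. Low-level genes such as VLDLR, COL3A1 and HULC lost calls under 1 to 3 alternatives.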

Other observations

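The tests of hepatocyte mRNAs and the test of scaling for small RNAs were chosen after the results were seen. Genes named as hosts of small nucleolar RNAs (snoRNAs) were grouped by name after their values were seen. Of 23 tested genes named SNHG or GAS5, 16 fell, 4 rose and 3 did not pass the edgeR test (median log2 change -0.96). Of 71 tested snoRNA genes, 60 rose, 1 fell and 10 did not pass. The snoRNAs were not matched to these hosts, and the difference between the groups was not tested.

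The share of risen lncRNAs differed with the direction of the neighbouring gene. Among changed lncRNAs whose nearest tested protein-coding gene within 50 kb rose, 89.1% rose (640 of 718), against 52.4% (272 of 519) where that gene fell, so beside a fallen gene about as many lncRNAs rose as fell. The odds ratio was 7.45 (two-sided Fisher's exact test across genes, p = 4.58e-48, where genes are not independent). Across 2617 pairs, Spearman's rho of the log2 changes was 0.39. It was 0.682 for 584 pairs overlapping on the same strand and 0.297 for 1040 on opposite strands.

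With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real split gave 12669 changed genes and the highest of the others 0. For lncRNAs the values were 1758 and 0, and for ferroptosis and iron genes 91 and 0. In each case 1 of 10 splits, the real one, gave as many. Every other split puts libraries of both oxygen conditions in each group, which widens the spread within groups. The values of 0 are therefore built in and say nothing on chance. For lists the real split gave 13 and the highest other 10, with at least 7 in every other split, and again 1 split gave as many. The preset-correlation list test therefore calls many lists on splits that mix the oxygen conditions. Each such split still has unequal numbers of hypoxia libraries in its groups, so part of the oxygen difference remains. These calls therefore cannot show how often the list test errs.

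Most hepatocyte mRNAs of the fixed list were near 0 in libraries labelled Huh7, with exceptions such as CPS1 and C3. A general loss of nearly all reads of a gene to transcripts without a gene name is argued against. Of 156 members of the replication, oxidative phosphorylation and ribosomal protein lists 0.64% lay below the filter, against 71.7% of hepatocyte genes (Fisher's exact test, p = 3.43e-30). Abundant genes would pass the filter with part of their reads lost, and the transcripts without a gene were not searched for hepatocyte mRNAs. A loss confined to hepatocyte mRNAs is therefore not excluded. An admixture or swap in part of the libraries would leave these mRNAs in the others, but the highest value of ALB, AFP, APOA1, APOB or TTR in any library was 0.077 CPM, a value already seen. What also stays open is whether all 6 libraries came from another cell line or from a stock of the line that lost hepatocyte expression. Either would give 48 of 60 genes under 1 CPM. The abundance of ALPI, ALPP and CGA does not decide between them, and the table holds no genotype. No biological explanation was tested, as both groups share the pattern.

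Changed lncRNAs mostly rose. Low abundance does not account for the share of 73.4%, since 1000 draws of protein-coding genes matched on mean CPM gave a median share of 58.7% (95% of draws 56.3% to 60.8%), although that is above the 44.7% of all protein-coding genes. Neighbouring protein-coding genes do not account for the whole skew either, because the 252 changed lncRNAs with no tested protein-coding gene within 50 kb rose in 73.4% of cases (exact 95% interval 67.5% to 78.8%). The skew was shared by other biotypes, of whose changed genes 70.4% rose (processed pseudogenes 158 up and 81 down), so a rise particular to lncRNAs is not shown. What stays open is a cause common to noncoding genes, whether in the cells or in the libraries, which was not tested.

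Small structured RNAs rose. The choice among the scalings is argued against as the cause, since the list's lowest median log2 change under TMM, median-of-ratios and library totals was 0.80. Over the other tests and scalings, some of which also used another filter, the lowest was 0.60. The median of all genes was 0.025 with TMM and -0.13 with library totals, so a larger shift common to all genes was not tested. A better recovery of short RNAs in the hypoxia libraries may explain the rise, as the median log2 change of 71 snoRNA genes was 1.25 (bootstrap 95% interval 1.13 to 1.33). The bootstrap resampled snoRNA genes, which are not independent, and leaves out the spread between libraries. A rise of these RNAs in the cells would look alike, and library preparation and oxygen cannot be separated in this design.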
